A study of Mus musculus with 20 samples.

How the data were processed

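Gene expression was measured on Affymetrix arrays in C2C12, a mouse myoblast cell line that forms muscle fibres when serum is lowered. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was prepared. siRNAs were transfected at 10 nM with RNAiMax, and differentiation in medium with horse serum began a day after transfection. The 20 samples form 2 sets. The scramble set holds 8 arrays, all at day 2 of differentiation: cells transfected with a scramble siRNA (siScr) or with 1 of 3 siRNAs against the long noncoding RNA Myolinc (siMyolinc.1, siMyolinc.2, siMyolinc.3). The time-course set holds 12 arrays: untransfected cells in growth medium at day 0 (Undiff), at day 1 (Day_1) and at day 2 (Day_2), and the same 3 siMyolinc groups at day 2. Each group has 2 arrays, which the labels call biological replicates.

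The siMyolinc arrays occur in both sets. After subtraction of each transcript cluster's mean over the 6 arrays, arrays with the same label in the 2 sets correlated at 0.933 to 0.949, and arrays with different labels at most at 0.289, over 35532 transcript clusters. They were treated as the same hybridisations, which leaves 14 distinct arrays, and no comparison of groups counted an array more than once.

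The deposited values are log2 expression values per transcript cluster, made by the authors with RMA, and compared by them with limma, per the submitters' processing notes; versions, annotation and genome build are not given in the sources used here. The sets were summarised separately: array medians over 35556 transcript clusters lay at 6.93 to 6.97 in the scramble set and at 7.42 to 7.51 in the time-course set. Levels were therefore compared only within a set. The authors' sheets give 1 transcript cluster per gene symbol for 20193 symbols, with the log2 differences and unadjusted p-values of the authors' comparisons, per the file headers. For 706 symbols the 2 sheets name different transcript clusters. In all 706 the cluster of the scramble sheet is the one with the larger SD over its own 8 arrays, which ties the choice of cluster to the spread of these arrays. In both sheets 23 gene symbols had been turned into dates, and for these the gene name of the sheet was used. In 1 siMyolinc.3 array of the time-course set 23 cells held day numbers and were set to missing. No column of per-sample values was left unused (0 columns). Of the symbols, 17433 are current in the reference gene table (GRCm38.p6), 2048 are older names and 712 were not matched; the names of the sheets were kept, and the table was used for names only.

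Groups were compared with limma (version 3.58.1, R version 4.3.3) on the deposited log2 values, with 1 coefficient per group and all arrays of a set in the fit, so that the groups share an estimate of the spread. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all 20193 genes of the sheet. The siMyolinc mean weights the 3 siRNAs equally; its test measures the spread between arrays within a siRNA, not the spread between siRNAs, and an alternative with the 6 arrays as 1 group was fitted for that reason. Differences among the siRNAs were tested with the moderated F test. All adjusted p-values of genes in the report come from these limma fits, and ± marks the standard error of a log2 change unless an SD is named. With 2 arrays per group, the number of arrays limits the precision: the median standard error of a log2 change was 0.0710 for the siMyolinc mean against siScr and 0.0801 between 2 groups of the time-course set.

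Gene lists (24, fixed before the data were examined) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation. The named genes follow a rule fixed at the same time: the 12 called genes with the largest rise and the 12 with the largest fall whose arrays did not overlap between the sides, for siMyolinc against siScr, Day_2 against Undiff and siMyolinc against Day_2; Filip1, Tardbp and Myolinc in each; and up to 4 called members of each list with the largest absolute change. Tardbp and Myolinc itself were not analysed here, so the depth of the knockdown is not reported. Some genes that the rule names are not reported here. A further 8 lists, all tests of explanations and 2 alternatives for the choice of transcript cluster were chosen after the data had been seen. The rule also asked for the brightest of a gene's transcript clusters, and since each sheet holds 1 per gene it made no choice here.

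The fits were tested on simulated data with the real means and spreads and 200 changed genes among all genes. For the siMyolinc mean against siScr (20193 genes), 5.97% of genes changed by 0.25 log2 were called, 98.5% of those changed by 0.5, and all 66 changed by 1, with 15 unchanged genes called. For siMyolinc.2 against siScr, 85.1% of genes changed by 0.5 were called. For Day_2 against Undiff (20170 genes), 92.5% of genes changed by 0.5 were called, with 4 unchanged genes called.

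Alternatives tried were the replicate number as a block, each array left out in turn, a filter on dim transcript clusters, quantile normalization of the values once more, centring on each array's 75th percentile, an intensity trend with a robust prior, array weights, another transcript cluster per gene, only the arrays of the groups compared, a minimum change of 1 log2, and all transcript clusters of the series matrix. Changes were compared across the sets only as log2 differences, each fitted within its own set. Figures were drawn with matplotlib (version 3.10.9).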

Results

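Expression was measured on arrays in C2C12 myoblasts during differentiation, with and without knockdown of the long noncoding RNA Myolinc. The scramble set held 2 arrays each of siScr, siMyolinc.1, siMyolinc.2 and siMyolinc.3 at day 2, and the time-course set held 2 arrays each of Undiff, Day_1, Day_2 and the 3 siMyolinc groups. Replicate arrays correlated across genes at 0.996 to 0.999. The p-values measure the spread between these pairs of arrays. Myolinc itself and Tardbp were not analysed here.

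The comparison of siMyolinc with siScr at day 2 asked which transcripts change when the lncRNA is knocked down. Genes of muscle contraction, cell division and cholesterol synthesis were lower with the siMyolinc siRNAs. Among the largest falls were Actc1, cardiac alpha-actin, at -1.70 ± 0.07 log2 (adjusted p = 1.1e-05), the myosin light chains Myl4 (-1.59 ± 0.07) and Myl1 (-1.55 ± 0.10), Trdn, the sarcoplasmic reticulum protein triadin (-1.96 ± 0.23), and Tmem8c, the fusion protein myomaker (-1.60 ± 0.10). The matricellular protein gene Postn fell by 2.33 (± 0.16) and the imprinted noncoding RNA H19 by 2.13 (± 0.19). The largest rises were in Havcr2, an immune receptor gene also called Tim-3 (2.56 ± 0.06, adjusted p = 2.3e-07), the collagenase Mmp13 (2.12 ± 0.13) and Spp1, which encodes osteopontin (1.76 ± 0.12). For Havcr2 (transcript cluster 10375443) the log2 level was 6.31 ± 0.05 (SD, n = 2) in siScr and 8.87 ± 0.94 (SD, n = 6) over the siMyolinc arrays; for Postn (10492021) it was 9.87 ± 0.50 (SD, n = 2) and 7.54 ± 0.45 (SD, n = 6).

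The other genes with the largest rises were Tnfrsf23, Snora75, Slpi, Car8, Anpep, Fgf7, Atp1b1, Angptl4 and Layn, at 1.47 down to 1.24 log2. Further large falls were in Scn7a (-2.00), Igfbp2 (-1.67), Gulp1 (-1.67) and Lrrc17 (-1.62). Filip1 changed by -0.09 ± 0.10 log2 and was not called (adjusted p = 0.672).

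**Figure D1:**
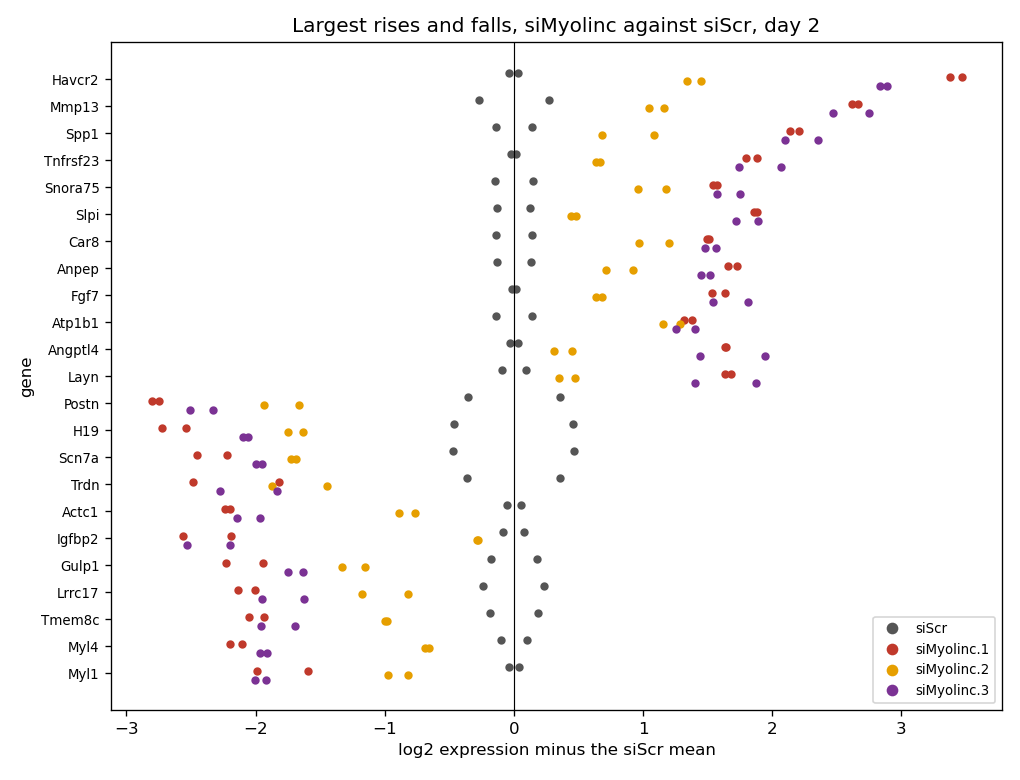
Horizontal axis: log2 expression on each array of the scramble set minus the siScr mean of that gene. Each row is a gene, and each point is an array, coloured by group (2 arrays per group). Havcr2 rose by 3.42 log2 with siMyolinc.1, 1.39 with siMyolinc.2 and 2.86 with siMyolinc.3. The 23 genes were chosen among those whose siMyolinc and siScr arrays do not overlap.

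Of the sarcomere list, 18 of 43 measured genes fell and none rose (21 fell and 1 rose, adjusted over the list alone), with a median change of -0.18 and a camera adjusted p of 6.2e-11 (0.0286 with an estimated correlation). Tnnc1, slow and cardiac troponin C, fell by 1.55 (± 0.12). Among myogenic regulators 2 fell and 2 rose of 15, and the list was not called (adjusted p = 0.191). Myog, which drives terminal differentiation, fell by 1.08 (± 0.08), while Mef2d rose by 0.26 (± 0.06) and Tead4 by 0.23 (± 0.06). Of 13 fusion and adhesion genes 4 fell and 1 rose, including Ncam1 (-1.07) and Cdh15, M-cadherin (-0.81). That list's adjusted p was 0.0137, and adjusted p = 0.204 with an estimated correlation. Of 17 calcium handling genes 5 fell and 1 rose, among them Casq2 (-1.01), with an adjusted p of 0.0017 and adjusted p = 0.0769 with an estimated correlation; without dim transcript clusters it was 0.276.

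Cell cycle genes fell in 26 of 40 cases and none rose (31 and none, adjusted over the list alone), with a median of -0.45 and a camera adjusted p of 1.5e-24 (0.0286 with an estimated correlation). Examples were the cyclin Ccna2 (-1.50 ± 0.09), the checkpoint kinase Bub1 (-1.32 ± 0.14), Prc1 (-1.20 ± 0.12) and Top2a (-1.20 ± 0.08). In the cholesterol synthesis list 19 of 20 genes fell (19 adjusted over the list alone), with a median of -0.71 and a camera adjusted p of 1.5e-24 (0.0286 with an estimated correlation). Lss, lanosterol synthase, fell by 1.29 (± 0.07), Dhcr7 by 1.11 (± 0.08) and Idi1 by 0.94 (± 0.07). Interferon response genes fell in 17 of 39 cases and 1 rose, with a median of -0.20 and a camera adjusted p of 3.1e-08 (0.0286 with an estimated correlation). They included Ifi44 (-1.50 ± 0.10), Oasl2 (-1.09 ± 0.10), the RNA sensor Ddx58 (-0.92 ± 0.07) and Stat2 (-0.79 ± 0.07).

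Nonmuscle actomyosin genes fell in 11 of 17 cases (median -0.28, camera adjusted p = 1.9e-10, 0.0286 with an estimated correlation), among them Myl9 (-1.06), Tagln (-0.92) and Myh10 (-0.60). In the extracellular matrix list 15 of 34 fell and 1 rose (camera adjusted p = 1.8e-09, and adjusted p = 0.0794 with an estimated correlation). Decorin, Dcn, fell by 1.13, Col1a1 fell by 0.95, and Col8a1 rose by 0.99. Smooth muscle markers fell in 4 of 9 cases, led by Des, desmin (-1.32), with an adjusted p of 0.0017 (adjusted p = 0.0769 with an estimated correlation). This is not a separate result, since Des is also in the sarcomere list and Acta2, Tagln and Actg2 are also in the actomyosin list. Des fell by 2.00 with siMyolinc.1 and 1.82 with siMyolinc.3, but with siMyolinc.2 it was not called (-0.15, adjusted p = 0.532). Immediate early genes rose in 4 and fell in 1 of 18 cases (camera adjusted p = 0.0321, and adjusted p = 0.204 with an estimated correlation). That call was also lost with 75th percentile centring (0.0521), without siScr replicate 2 (0.0754) and without siMyolinc.3 replicate 1 (0.0595). Nr4a1 rose by 0.89 and Dusp6 by 0.81, while Egr1 fell by 0.98.

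The other 14 lists were not called by camera. For these, adjusted p ran from 0.0516 for p53 targets to 0.901 for the endothelial markers and for the list of Filip1 and its 6 neighbours, none of which was called. Chrnd rose (0.47) and Lrp4 (-0.56) and Chrng (-0.52) fell among neuromuscular junction genes, and Ppargc1a (0.86) rose and Ckm (-0.50) fell among muscle metabolism genes. Of these, Chrnd, Lrp4 and Chrng were not called with siMyolinc.2 alone (adjusted p = 0.715, 0.0595 and 0.93). The unfolded protein and ATF4 list had 1 gene higher and 5 lower of 19 (median -0.09). Among markers of other cell types, Cd68 (0.51) and Cd14 (0.43) of the macrophage list and Runx2 (0.34) and Spp1 of the osteoblast list rose, and none of the adipocyte or endothelial markers was called. Without dim transcript clusters the osteoblast (camera adjusted p = 0.00568) and macrophage lists (camera adjusted p = 0.014) were called higher. That filter removed members of both lists, and the medians went from 0.03 to 1.05 and from -0.01 to 0.47. These calls therefore describe the brighter members left and not the whole lists. For the list of Filip1 and its neighbours and the adipocyte, macrophage and endothelial lists the median was just below 0 while the test pointed up.

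In all, 1836 of 20193 genes were called, 736 higher and 1100 lower, and 70 of these changed at least by 1 log2. The split moved from 40.1% higher to 53.5% higher when each array was centred on its 75th percentile. Without siScr replicate 2 the count was 825, and without siMyolinc.2 replicate 2 it was 1209, where the array left in the group was assumed to vary like the others. With the 6 siMyolinc arrays as 1 group, so that spread between siRNAs counted as error, 410 genes were called; the authors' deposited table holds 2935 genes at an unadjusted p under 0.05 for the same comparison, and 106 after adjustment here.

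**Figure D2:**
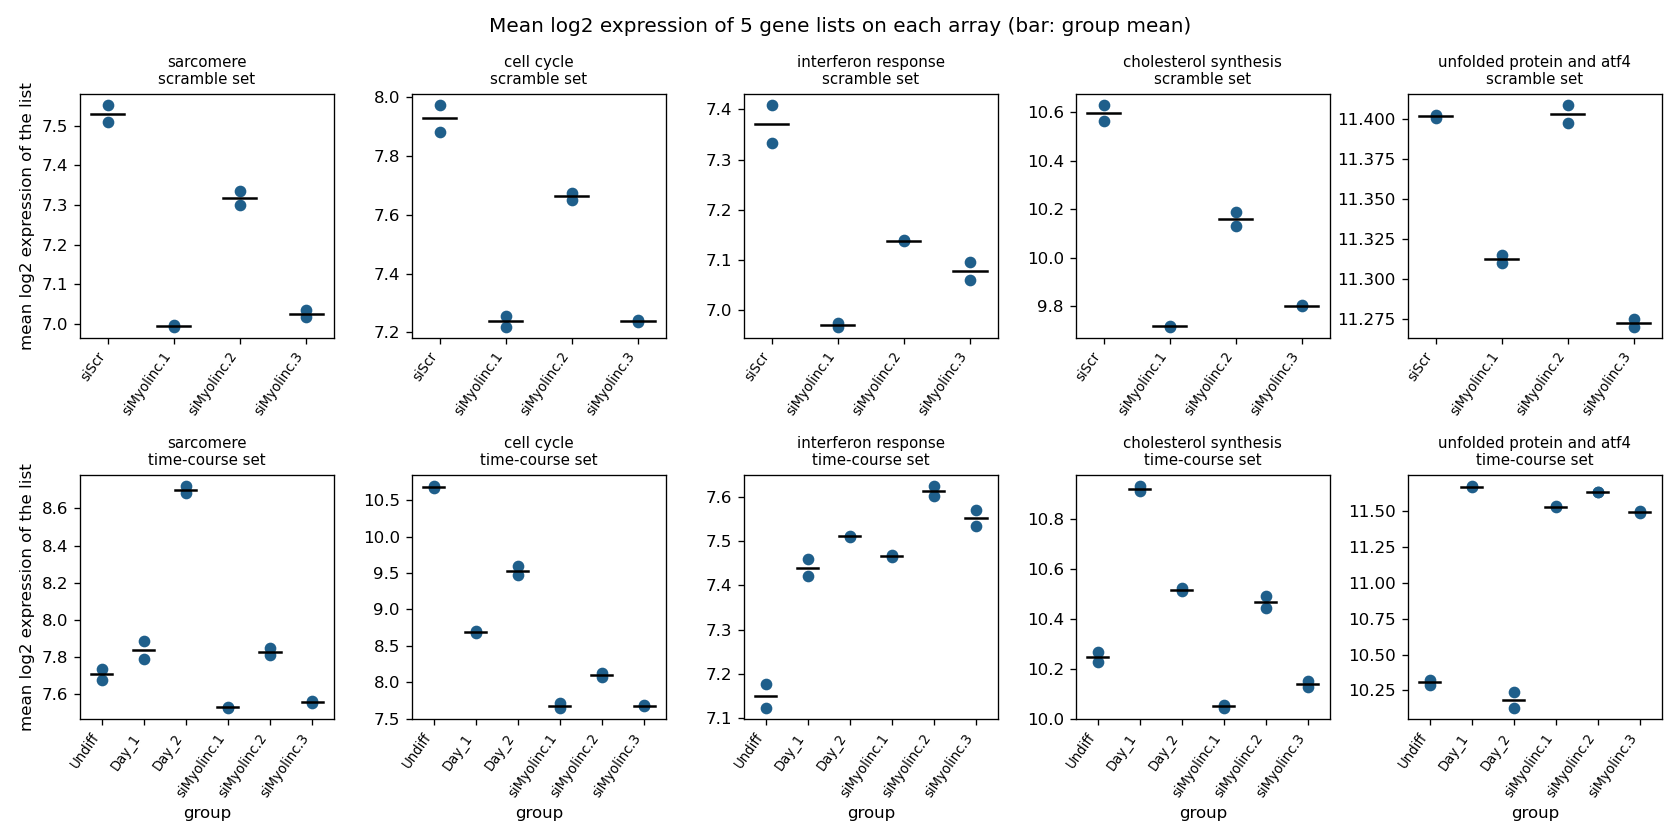
Mean log2 expression of the measured genes of 5 lists on each array (points, 2 per group) and the group mean (bar), in the scramble set (upper panels) and the time-course set (lower panels); vertical axes differ between panels. The unfolded protein and ATF4 genes stand high in Day_1 and in the siMyolinc groups and low in Undiff and Day_2, while in the scramble set their median change is -0.09.

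The 3 siRNAs were then compared with siScr and with one another. siMyolinc.1 changed 2276 genes (837 higher, 1439 lower), siMyolinc.3 changed 1839 (742 higher, 1097 lower), and siMyolinc.2 changed 272 (145 higher, 127 lower). Havcr2, Mmp13, Spp1 and Actc1 were called with each of the 3. Slpi, Angptl4, Layn and Igfbp2 were called with siMyolinc.1 and siMyolinc.3 but not with siMyolinc.2, and the F test among the siRNAs was called for all 4 genes (Igfbp2: -2.38, -0.28 and -2.36, adjusted p = 0.00018). The same held for Des, Ncam1, Cdh15, Col8a1, Chrnd and Chrng (Chrng: -0.79, -0.04 and -0.74, F test adjusted p = 0.000864). It also held for the cell cycle genes Bub1 (-1.73, -0.49 and -1.73, F test adjusted p = 0.0053) and Prc1 (-1.52, -0.67 and -1.42, F test adjusted p = 0.0179). Atp1b1 rose by 1.35, 1.22 and 1.33, with no difference called (adjusted p = 0.736). For siMyolinc.1 the share of higher calls went from 36.8% to 53.9%, and for siMyolinc.3 from 40.3% to 53.7%, with 75th percentile centring; for siMyolinc.1 it was 47.5% after quantile normalization once more. The count for siMyolinc.1 was 1313 without siScr replicate 2, and 997 and 1007 without its own replicates 1 and 2. For siMyolinc.3 it was 1141 without siScr replicate 2 and 1202 without its own replicate 2. For siMyolinc.2 it was 64 without siScr replicate 2, 178 without either siMyolinc.1 array, and 47 and 36 without its own replicates 1 and 2. With other settings the count for siMyolinc.2 was 518 (dim transcript clusters left out), 513 (intensity trend and robust prior), 142 (only the arrays compared) and 21 (whole series matrix), and for siMyolinc.3 it was 1115 with array weights and 913 with only the arrays compared.

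All 3 siRNAs changed 208 genes in the same direction, 94 higher and 114 lower. The shared count was 383 without dim transcript clusters, 378 with an intensity trend and robust prior, 101 with only the arrays compared and 16 over the whole series matrix. From 3 independent lists 0.71 genes would be shared. A simulation with no effect and the shared siScr arrays gave 0 genes. Without any effect the adjusted threshold calls hardly any gene for a siRNA, so this 0 was nearly fixed beforehand. It cannot show how many of the 208 genes the shared siScr arrays brought in. Changes with siMyolinc.1 and siMyolinc.3 correlated across genes at r = 0.883, where unchanged groups against the same siScr arrays give 0.496; their covariance was 0.0501 against 0.0047 simulated. For siMyolinc.1 and siMyolinc.2 the r was 0.644 (simulated 0.493, covariance 0.0232 against 0.0047), and for siMyolinc.2 and siMyolinc.3 it was 0.595 (simulated 0.490, covariance 0.0201 against 0.0047). Part of the excess over independent lists may come from the shared siScr arrays, since 2 arrays cannot be split into groups of 2. Differences among the siRNAs were called for 816 genes, and 10 genes were called in opposite directions by 2 siRNAs. The shared count was 52 without siScr replicate 2, 127 and 121 without siMyolinc.1 replicates 1 and 2, and 37 and 29 without siMyolinc.2 replicates 1 and 2. The count of differences was 405 and 433 without siMyolinc.1 replicates 1 and 2, and 190 and 154 without siMyolinc.2 replicates 1 and 2; it was 1274 without dim transcript clusters, 1319 with the trend, 1346 with array weights and 210 over the whole series matrix.

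**Figure D3:**
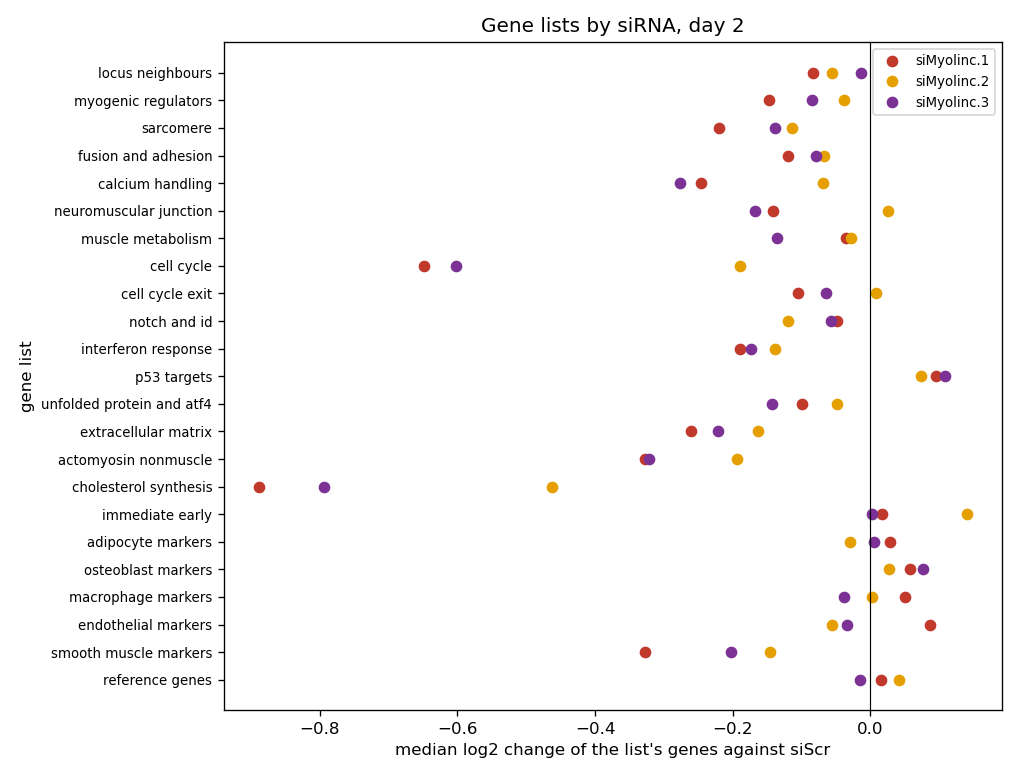
Median log2 change of the measured genes of each list against siScr (horizontal axis), by siRNA (colour), in the scramble set. With siMyolinc.1 and siMyolinc.3 the cholesterol synthesis and cell cycle lists lie lowest, and siMyolinc.2 lies nearer 0 than these siRNAs in both.

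The time course asked how untransfected cells change as they differentiate. From Undiff to Day_2, contractile and calcium handling genes rose and cell cycle genes fell. Scn7a, a sodium channel gene, rose by 5.80 (± 0.17, adjusted p = 2.8e-09), decorin, Dcn, by 5.03 (± 0.08), Myl1 by 4.77 (± 0.08), Trdn by 3.81 (± 0.23), the embryonic myosin heavy chain Myh3 by 3.34 (± 0.13) and Tmem8c by 3.25 (± 0.09). Myl1 (transcript cluster 10355259) went from a log2 level of 6.29 ± 0.06 (SD, n = 2) to 11.06 ± 0.03 (SD, n = 2). Id2 and Id3, inhibitors of myogenic basic helix-loop-helix factors, fell by 3.54 (± 0.07) and 2.86 (± 0.10), and the quinone reductase Nqo1 fell by 2.95 (± 0.09). Filip1 rose by 0.39 (± 0.09, adjusted p = 0.00619), and was not called without Undiff replicate 1 (0.30, adjusted p = 0.0666) or without Day_2 replicate 2 (0.37, adjusted p = 0.0503).

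Sarcomere genes rose in 27 of 43 cases and 1 fell (27 and 1, adjusted over the list alone; median 0.62, camera adjusted p = 2.4e-15, 0.0358 with an estimated correlation). Calcium handling genes rose in 11 of 17 cases, among them Casq2 (2.66) and Atp2a1, the fast muscle calcium pump (1.44), and neuromuscular junction genes rose in 6 of 9, with Lrp4 at 2.00 and Chrnd at 1.82; both lists had an adjusted p of 0.0309 with an estimated correlation. Of 15 myogenic regulators 7 rose and 2 fell (camera adjusted p = 0.0040, 0.0499 with an estimated correlation, and 0.113 without dim transcript clusters), with Myog at 1.64 and Mef2a at 0.87. All 40 cell cycle genes fell (median -1.22, camera adjusted p = 8.2e-29, 0.0309 with an estimated correlation), as Mybl2 (-1.74) and Aurka (-1.58). Interferon response genes rose in 17 of 39 cases, with Ifit3 at 3.00 and Ifit1 at 1.73 (camera adjusted p = 4.8e-05, 0.0309 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 20 cases and 1 fell, as Fdft1 (0.64) and Insig1 (0.62) (camera adjusted p = 8.9e-05, 0.0499 with an estimated correlation). In the list of Filip1 and its 6 neighbours 5 of 7 genes rose, Filip1 among them, with Myo6 at 0.88 and Senp6 at 0.51 (camera adjusted p = 0.00864, and adjusted p = 0.0659 with an estimated correlation).

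The remaining 16 lists were not called. Extracellular matrix genes went both ways, 13 higher and 12 lower of 34, with Mmp2 at 1.46 and Timp3 at -1.29. Within the Notch and Id list 9 fell and 5 rose of 20 (adjusted p = 0.052), with Twist2 at -1.42, and of 12 cell cycle exit genes 6 rose and 4 fell, with Gadd45a at 2.28. The other genes with the largest rises were Myl4, Clec2d, Actc1, Sema3d, Gm10554 and Sepp1 (3.55 to 3.03), and those with the largest falls were Ccnb1ip1, Aqp1, Krt14, Peg10, Lgr6, Fgf7, Fam198b, Tigit and Cenph (-2.84 to -1.84). Pparg fell by 1.05 among the adipocyte markers, and Cd14 fell by 0.39 and Cd68 by 0.34 among the macrophage markers. The test called 6043 genes, 2982 higher and 3061 lower.

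Day 1 differed from both day 0 and day 2. A culture or array batch of the Day_1 arrays cannot be told apart from the day in any comparison with Day_1, and the labels give no batch. On the first principal component of the set these arrays lay on the side of the siMyolinc arrays, away from Undiff and Day_2. From Undiff to Day_1 all 40 cell cycle genes fell (median -2.05, camera adjusted p = 2.6e-35, 0.0252 with an estimated correlation), led by Rrm2 (-3.34 ± 0.11) and Mcm5 (-2.81 ± 0.07), and Id2 fell by 4.46 (± 0.07). Unfolded protein and ATF4 genes rose in 17 of 19 cases and none fell, with Slc7a11 at 2.68 (± 0.10), Dnajb9 at 2.51 (± 0.07) and Atf3 at 2.51 (± 0.08); the camera adjusted p was 4.8e-11, and adjusted p = 0.0845 with an estimated correlation. Cholesterol synthesis genes rose in 16 of 20 cases, as Mvd (1.78) and Insig1 (1.40), with an adjusted p of 4.8e-06 (adjusted p = 0.0727 with an estimated correlation). Myod1, a founder factor of the muscle lineage, fell by 2.17 (± 0.07), while Myf5 rose by 1.01 (± 0.07).

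Extracellular matrix genes fell in 23 and rose in 5 of 34 cases from Undiff to Day_1, with Ctgf at -3.27 (camera adjusted p = 4.4e-08, and adjusted p = 0.0898 with an estimated correlation). Nonmuscle actomyosin genes fell in 13 of 17 cases, as Lmna (-1.12) and Cnn1 (-1.10), with adjusted p = 0.0898 with an estimated correlation. Notch and Id genes fell in 11 and rose in 3 of 20 cases, with Id3 at -2.92 and Hes1 at -1.61 (adjusted p = 0.0727 with an estimated correlation). Calcium handling genes rose in 11 of 17 cases (adjusted p = 0.226 with an estimated correlation) and interferon response genes rose in 19 and fell in 4 of 39, with Ifi44 at 1.86 (adjusted p = 0.153 with an estimated correlation). Smooth muscle markers fell in 5 of 9 cases, with Des at -2.18 (adjusted p = 0.301 with an estimated correlation), and reference genes fell in 7 and rose in 2 of 13, with Tfrc at -0.59 and Gusb at -0.50 (adjusted p = 0.24 with an estimated correlation). The test called 9720 genes, 5461 higher and 4259 lower. The median log2 change of all genes was 0.11, and centring on the 75th percentile moved it to 0.26 and the share of higher calls from 56.2% to 78.9%. Without Undiff replicate 1 the count was 6277.

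From Day_1 to Day_2, 37 of 40 cell cycle genes rose (median 0.79, camera adjusted p = 1.6e-19, 0.047 with an estimated correlation) and 28 of 34 matrix genes rose (median 0.70, adjusted p = 2e-14, 0.047 with an estimated correlation). Unfolded protein and ATF4 genes fell in 17 of 19 cases (median -1.38, camera adjusted p = 1.8e-13, and adjusted p = 0.0559 with an estimated correlation), with Slc7a11 at -3.41. Myogenic regulators rose in 10 and fell in 2 of 15 cases (adjusted p = 0.00033, 0.047 with an estimated correlation), with Myod1 at 1.91 and Myog at 0.86. Sarcomere genes rose in 27 and fell in 7 of 43 cases (median 0.72, adjusted p = 5.4e-10, and adjusted p = 0.0703 with an estimated correlation). The test called 10816 genes, 4266 higher and 6550 lower, with a median change of all genes of -0.12 that centring moved to -0.26, and the share of higher calls from 39.4% to 21.2%. Without Day_1 replicate 2 the count was 7067, without Day_2 replicate 2 it was 6926, and without dim transcript clusters it was 6792.

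Knocked-down cells at day 2 were also compared with untransfected cells at Day_2, so that here transfection goes with the siRNA. Matrix and cell cycle genes were lower in the siMyolinc groups and stress-response genes were higher. Many muscle genes fell too, but the sarcomere list had adjusted p = 0.0516 with an estimated correlation, and the other muscle lists were not called with it either. Among the largest falls were Scn7a (-5.55 ± 0.14, adjusted p = 1.7e-10), Postn (-4.82 ± 0.10), Pdlim3 (-4.59 ± 0.07), H19 (-4.37 ± 0.08), Myl1 (-4.15 ± 0.07) and the cyclin gene Ccna2 (-3.62 ± 0.08). Slc7a11, the cystine transporter, rose by 4.14 (± 0.09), the carbonic anhydrase Car6 by 4.32 (± 0.11) and Ptgs2, which encodes cyclooxygenase 2, by 2.97 (± 0.05). Filip1 fell by 0.25 (± 0.07, adjusted p = 0.022), and was not called without Day_2 replicate 1 (-0.27, adjusted p = 0.0816), without Day_2 replicate 2 (-0.22, adjusted p = 0.163) or with 75th percentile centring (-0.20, adjusted p = 0.0618).

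In this comparison cell cycle genes fell in 39 of 40 cases (median -1.67, camera adjusted p = 2.6e-32, 0.0318 with an estimated correlation), matrix genes fell in 30 and rose in 2 of 34 (median -0.95, adjusted p = 9.3e-19, 0.0369 with an estimated correlation), and nonmuscle actomyosin genes fell in 16 of 17 (adjusted p = 2.8e-12, 0.0472 with an estimated correlation). Sarcomere genes fell in 27 and rose in 3 of 43 cases (median -0.66, adjusted p = 2.7e-13, and adjusted p = 0.0516 with an estimated correlation), with Acta1 at -3.00 and Des at -2.93. Myogenic regulators fell in 10 and rose in 3 of 15 cases, with Myod1 at -2.24 (adjusted p = 0.0042, and adjusted p = 0.0519 with an estimated correlation and 0.139 without dim transcript clusters). Unfolded protein and ATF4 genes rose in 17 of 19 cases (median 1.36, adjusted p = 1.8e-14, 0.0472 with an estimated correlation), with Ppp1r15a at 2.40 and Pdia6 at 2.38. Interferon response genes went both ways, 8 higher and 9 lower of 39 (adjusted p = 0.79), with Ifit2 at 1.45 and Irf1 at -1.64.

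Fusion, calcium handling, neuromuscular junction, Notch and Id, cholesterol synthesis and smooth muscle lists were lower by camera in this comparison, with adjusted p from 1.7e-05 to 0.0103, but their adjusted p was 0.0516 to 0.148 with an estimated correlation. Without dim transcript clusters it was 0.952 for calcium handling, 0.0597 for neuromuscular junction and 0.063 for cholesterol synthesis genes. Examples were Tmem8c (-2.64), Casq2 (-2.46), Lrp4 (-2.18) and Hes1 (-1.51). The other genes with the largest rises were H2-M10.1, Ppef1, Gfral, Try5, Sdf2l1, Fam198b, Slc22a23, Steap1 and Acox2 (3.99 to 2.87), and those with the largest falls were Cmah, Lrrc17, Aspn, Sema6a, Car3 and Kif11 (-4.29 to -3.48). In all, 7701 genes were called, 3888 higher and 3813 lower, with 7106, 5973 and 7054 for siMyolinc.1, siMyolinc.2 and siMyolinc.3 alone. With 75th percentile centring the share of higher calls went from 50.5% to 60.5% for the mean and from 49.4% to 61.6% for siMyolinc.1. On the first principal component of the set, with 60.0% of the variance, Undiff and Day_2 arrays lay at -48.0 to -31.6, and Day_1 and siMyolinc arrays at 9.80 to 26.6; the cell cycle, matrix and unfolded protein lists differed between the same arrays.

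Against Undiff, the siMyolinc groups at day 2 had all 40 cell cycle genes lower (median -2.94, camera adjusted p = 3.5e-37, 0.022 with an estimated correlation) and 13 of 20 Notch and Id genes lower (adjusted p = 1.4e-05, 0.0359 with an estimated correlation). Among these, Id2 was at -3.87 and Id3 at -3.16. Unfolded protein and ATF4 genes were higher in 16 and lower in 1 of 19 cases (median 1.07), with Slc7a11 at 3.40 and Atf3 at 2.05 (adjusted p = 5.1e-10, and adjusted p = 0.0724 with an estimated correlation). Matrix genes were lower in 28 and higher in 3 of 34 cases (adjusted p = 1.9e-11, and adjusted p = 0.0681 with an estimated correlation), with Postn at -3.53. Sarcomere genes were split, with 9 higher and 11 lower of 43 (adjusted p = 0.676). The test called 8147 genes, 4073 higher and 4074 lower, and the share of higher calls went from 50.0% to 60.7% with 75th percentile centring.

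The knockdown change against siScr was set beside the change of untransfected cells from Undiff to Day_2. The 2 log2 changes share no array. The calls are not separate in this way, since the spread in each set was also estimated from the 6 siMyolinc arrays. Genes such as Actc1, Myl1, Myl4, Trdn, Tmem8c and Scn7a, which rose with differentiation, were lower with siMyolinc. Of 1100 genes lower with siMyolinc, 521 were higher at Day_2 than in Undiff, where independent lists would share 162 (Fisher's exact test, p = 8.7e-157), and 254 were lower in both, where 167 would be shared (p = 9.7e-13). Of 736 genes higher with siMyolinc, 231 were lower at Day_2 against 112 for independent lists (Fisher's exact test, p = 1.5e-29), and 166 were higher in both against 109 (p = 9.2e-09). These p-values treat genes as independent units, which they are not, and do not measure the spread between arrays. Every overlap exceeded that of independent lists, at ratios of 3.21 and 2.07 for opposite directions and 1.52 and 1.53 for the same direction. Genes with a low spread in the siMyolinc arrays may be called in both lists whatever the direction, and this was not tested. Only the difference between these ratios therefore bears on direction. Among the 100 genes most induced at Day_2, 55 were lower with siMyolinc and 8 higher, and among the 100 most reduced 33 were lower and 15 higher. Across genes, which are not independent replicates, Pearson's r was -0.164 and Spearman's rho was -0.0792. The knockdown change against siScr and that against untransfected Day_2 share the 6 siMyolinc arrays. Their changes correlated at r = 0.536, where unchanged groups that share these arrays give 0.265, with a covariance of 0.0450 against 0.00168 simulated. Lower in both were 850 genes, Scn7a and Postn among them, where independent lists would share 208, and 524 were higher in both, Havcr2 and Mmp13 among them, where 142 would be shared.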

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

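All tests of explanations in this part, and their thresholds, were chosen after the results had been seen, and what they favour is a hypothesis.

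The effect of the knockdown differed among the 3 siRNAs for 816 genes by the moderated F test. Of the genes with the largest changes, 17 were among them, and the gap between the siRNA with the highest and the siRNA with the lowest log2 change is given for each. For the rising genes it was 2.03 for Havcr2, 1.54 for Mmp13, 1.34 for Spp1, 1.25 for Tnfrsf23, 0.59 for Snora75, 1.41 for Slpi, 0.87 for Anpep, 1.02 for Fgf7, 1.31 for Angptl4 and 1.25 for Layn. For the falling genes it was 1.39 for Actc1, 2.09 for Igfbp2, 0.84 for Gulp1, 1.08 for Lrrc17, 1.00 for Tmem8c, 1.48 for Myl4 and 1.06 for Myl1.

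Outside the sheets' named genes, the series matrix holds 14657 further transcript clusters, which are not among the 20193 genes compared in the report. For siMyolinc against siScr 12 of these were called, 9 higher and 3 lower, with 1924 at an unadjusted p under 0.05. For Day_2 against Undiff 1211 were called, 594 higher and 617 lower.

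Cell cycle, cholesterol synthesis, sarcomere and interferon genes were lower with siMyolinc than with siScr. That the siScr arrays alone set the difference is argued against for cell cycle and sarcomere genes, which were also lower in siMyolinc.1 and siMyolinc.3 than in siMyolinc.2 (camera with an estimated correlation, adjusted p = 0.0377 for each list). Of the cholesterol synthesis genes, 14 of 20 were called lower in that comparison, and all lay below 0 (median -0.38, highest -0.08). These values argue against the siScr arrays alone for these genes, although the list missed the threshold with an estimated correlation (camera adjusted p = 0.0761). For interferon genes (adjusted p = 0.132, with 5 of 39 lower) that explanation stays open. For a brightness-dependent scaling difference, quantile normalization once more moved genes by up to 0.0657 log2 and cyclic loess by up to 0.0469. The cell cycle, cholesterol synthesis and sarcomere lists had medians of -0.45, -0.71 and -0.18. They stayed called by camera with an estimated correlation after both (adjusted p at most 0.0282 and 0.0296). Shifts this small could hardly end these calls, so the kept calls decide little. The small size of the shifts argues against such scaling as the whole cause for these lists, as far as the 2 corrections remove it. It stays open for interferon genes, called after quantile normalization (0.0367) and not after cyclic loess (0.0693, median from -0.20 to -0.17). With the 6 siMyolinc arrays as 1 group, the real split gave 410 called genes, and 1 of the 28 splits of the 8 arrays into 6 and 2, the real split itself, gave as many (highest of the others 15), but only 4 splits keep replicate arrays together (highest of the others 1), too few for a share under 0.05.

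Fewer genes were called with siMyolinc.2. The SD of its replicate difference, 0.126, was below those of siMyolinc.1 (0.133) and siMyolinc.3 (0.180). In the main fit this decides nothing, since the groups share an estimate of the spread (median standard error 0.0869 for each siRNA). With only the arrays compared, each siRNA had its own estimate, and siMyolinc.2 still had the fewest calls (142, against 1717 for siMyolinc.1 and 913 for siMyolinc.3). In that setting its low SD argues against noisier arrays. Over 1512 genes called in the same direction with siMyolinc.1 and siMyolinc.3, the siMyolinc.2 change had the same sign in 88.6% and a slope of 0.398 on the mean of the other changes, where 20 simulations with siMyolinc.2 unchanged and the siScr arrays shared gave 62.2% on average and a slope of at most 0.0534. A weaker form of the same change may therefore account for the lower count. The 816 genes that differ among the siRNAs leave changes specific to a siRNA open, and the depth of each knockdown was not analysed here.

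Unfolded protein and ATF4 genes were higher in siMyolinc than in untransfected Day_2. Loss of Myolinc is argued against as the whole cause, since the list's median change against siScr was -0.0872 (SD over genes 0.210), while against Day_2 it was 1.36 (SD 1.00). Transfection stays open, since neither set holds both siScr and untransfected Day_2 arrays. The untransfected Day_1 arrays were also 1.15 above Undiff (median, 17 of 19 genes higher, camera adjusted p = 0.0845 with an estimated correlation). Both of those groups are untransfected, so this comparison cannot tell whether transfection raised the list over Day_2. Chaperones of the endoplasmic reticulum were higher in Day_1 than in Undiff in 17 of 17 cases (0.00611), so a rise of that list also came without transfection. That list was chosen later and shares Hspa5, Hsp90b1, Pdia6 and Xbp1 with the unfolded protein list, so it is not separate evidence. A culture or array batch shared by the Day_1 and siMyolinc arrays cannot be told apart from the groups, and the labels give no batch. The first principal component, with 60.0% of the variance, puts Day_1 12.6 units from the siMyolinc mean and 43.0 from the nearer of the other untransfected groups. These distances restate the likeness that raised the question and do not test a batch.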

How the results depend on the processing

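The alternatives were fixed before the data were examined, except the 2 on the choice of transcript cluster, which left the knockdown count at 1817 and the correlation with differentiation at -0.163. Named genes were refitted with the replicate block, with arrays left out, without dim clusters, with both scalings, with the trend, with array weights and with the mean of a gene's clusters; 9495 of 9750 values kept their call, 255 lost it and 0 changed direction. Nearly all of these genes were picked because they were called with large changes in the same arrays, so kept calls are largely built in. A value here is a gene in a comparison under a setting, and 6092 of the values come from arrays left out. The counts over all genes, given below, moved more. Array numbers limit what the alternatives can show, and the cause of a shift was not tested.

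The count for siMyolinc.2 was 518 with dim transcript clusters left out, 513 with an intensity trend and a robust prior, 142 with only the arrays of the groups compared and 21 over all transcript clusters of the series matrix. For siMyolinc.3 it was 1115 with array weights and 913 with only the arrays compared. Genes shared by the 3 siRNAs numbered 383 without dim clusters, 378 with the trend, 101 with only the arrays compared and 16 over the whole matrix, and genes that differed among siRNAs 1274, 1319 with the trend, 1346 with array weights and 210 over the whole matrix. With the 6 siMyolinc arrays as 1 group 410 genes were called. Without dim clusters Day_2 against Day_1 gave 6792, and the correlation of knockdown and differentiation was -0.188; with siMyolinc.3 alone it was -0.129. The dim filter left no member of the list with Filip1 and Tardbp or of the endothelial list, which have no value there. It also took the calcium handling list, siMyolinc against Day_2, to the other direction of the test, with a median of -0.0602 and an adjusted p of 0.952, and ended the calls of calcium handling against siScr (0.276), of myogenic regulators for Day_2 against Undiff (0.113) and siMyolinc against Day_2 (0.139), and of neuromuscular junction (0.0597) and cholesterol synthesis genes (0.063) in the latter. Against siScr it brought calls of osteoblast (median 1.05, adjusted p = 0.00568) and macrophage markers (median 0.47, adjusted p = 0.014), which cover only the members it left. With an estimated correlation 5 lists were called against siScr and 4 against Day_2.

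With a change of at least 1 log2 required as well, the counts against siScr were 70 for the mean and 164, 21 and 126 for siMyolinc.1 to siMyolinc.3, with 14 shared and 68 differing. In the time-course set they were 983 for Day_1 against Undiff, 562 for Day_2 against Undiff, 742 for Day_2 against Day_1, 842 for siMyolinc against Day_2 (961, 742 and 913 by siRNA) and 1091 for siMyolinc against Undiff.

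With each array left out in turn, the ranges were 825 to 1974 for the siMyolinc mean, 997 to 2474 for siMyolinc.1, 36 to 258 for siMyolinc.2, 1141 to 1561 for siMyolinc.3, 29 to 188 for the shared genes and 154 to 824 for the differing genes. They were 6277 to 10479 for Day_1 against Undiff, 4432 to 6453 for Day_2 against Undiff, 6926 to 11507 for Day_2 against Day_1, 5591 to 8236 for siMyolinc against Day_2 and 6626 to 8641 against Undiff. The correlation ran from -0.175 to -0.122, the latter without siScr replicate 2.

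Replicate numbers showed no pairing common to all groups. Replicate differences of 2 groups correlated at -0.113 to 0.221 over 6 pairs of groups in the scramble set and at -0.167 to 0.237 over 15 in the time-course set. In each set 1 pair was over 0.1, siScr with siMyolinc.2 (0.221) and Undiff with Day_1 (0.237). A replicate batch shared by the groups of such a pair is not excluded. With a replicate block the counts were 1798 for the siMyolinc mean, 2195, 254 and 1872 by siRNA, 191 shared and 720 differing. They were 9499 for Day_1 against Undiff, 5904 for Day_2 against Undiff, 10610 for Day_2 against Day_1, 7570 for siMyolinc against Day_2 (6961, 5813 and 6929 by siRNA) and 8051 against Undiff. Blocked, 12 lists were called against siScr, with p53 targets (adjusted p = 0.0406) and osteoblast markers (0.0425) gained.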

Other observations

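The gene lists in this part were chosen after the data had been seen, so their tests describe these arrays only; adjusted p-values are over the 8 lists.

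Targets of the oxidative stress factor NRF2 were higher with the mean of the siRNAs. Against siScr 12 of 18 rose and none fell (median 0.35, camera adjusted p = 3.1e-10, 0.0491 with an estimated correlation), led by Nqo1 (1.06 ± 0.07), and followed by Osgin1 (0.45 ± 0.07), Gclm (0.44 ± 0.07) and Slc7a11 (0.44 ± 0.06). With siMyolinc.2 alone 1 of 18 rose (median 0.14, camera adjusted p = 0.0129, and adjusted p = 0.282 with an estimated correlation). Of the genes named here, Osgin1 (-0.093) and Gclm (-0.115) lay below 0 with siMyolinc.2, and Nqo1 (0.59) and Slc7a11 (0.22) above it. Differences between siRNAs were not tested for the lists of this part. In untransfected cells 14 of 18 fell from Undiff to Day_2 and none rose (median -0.90, 0.0108 with an estimated correlation). The matrix protease list, which also holds Plaur, a receptor gene and not a protease, went the other way. Against siScr 8 of 15 fell and 2 rose, with Adamts4 at -0.84, Plau at -0.66 and Adamts1 at -0.63 but Mmp13 at 2.12 and Plaur at 0.55. From Undiff to Day_2 10 of 15 rose and 1 fell, which was Plaur (-1.21). With siMyolinc.2 alone 2 members of that list fell and 2 rose (camera adjusted p = 0.0416, and adjusted p = 0.13 with an estimated correlation). Among integrin genes, Itga6 (1.17 ± 0.06) and Itgb7 (1.16 ± 0.06) rose against siScr and 4 of 15 fell, and the list was not called (adjusted p = 0.618).

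Small nucleolar RNA genes rose in 27 of 52 cases against siScr and none fell (median 0.35, camera adjusted p = 2.0e-24, 0.0441 with an estimated correlation), with Snora75 at 1.43, Snord14e at 0.98 and Snord118 at 0.96. With siMyolinc.1 and siMyolinc.3 32 and 28 of them rose, and with siMyolinc.2, which called fewer genes of any kind, 4 (median 0.11, camera adjusted p = 3.65e-08, and adjusted p = 0.13 with an estimated correlation). Ribosomal protein genes rose in 13 of 61 cases and none fell (median 0.10), with 1 gene called for siMyolinc.2. Chaperones of the endoplasmic reticulum fell in 4 of 17 cases against siScr (median -0.18; none was called for siMyolinc.2), as Dnajc3 (-0.26) and Xbp1 (-0.25), while against untransfected Day_2 16 of 17 rose (median 1.74, 0.0032 with an estimated correlation), as Sdf2l1 (3.08). They also rose in 17 of 17 cases in untransfected cells from Undiff to Day_1 (median 1.41, 0.00611 with an estimated correlation) and fell in 17 of 17 from Day_1 to Day_2. Amino acid genes of the ATF4 response had 1 member higher and 2 lower of 17 against siScr and all 17 higher against Day_2, and histone genes had 1 higher and 3 lower of 31 against siScr, 23 lower and none higher against Day_2 (0.0121 with an estimated correlation) and 25 lower and 2 higher from Undiff to Day_1 (0.0128).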
